A study of Mus musculus with 8 samples.

How the data were processed

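Total RNA of hand-dissected layer IV of the visual cortex was sequenced in wild-type and Otx2 heterozygous mice, per the labels. The deposited counts were raw read counts for each of 95533 Ensembl transcripts, per the file headers and the values. The submitters' processing notes name Bowtie, HTSeq, DESeq 1.8.3 and the mm10 build; the versions of Bowtie and HTSeq, their settings, the annotation release and the use of strand were not given in the sources used here. The authors' deposited tables of comparisons held, per the file headers, signal values (the mean per group of counts divided by size factors), the fold ratio of these means, its log2 value, and a p-value and adjusted p-value per transcript, in columns of the kind DESeq writes. Those tables were used only where the text names them. Transcript counts totalled 30651483 to 42374860 per library. The 2 heterozygous P100 samples of the 8 in the series were not analysed here.

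Reads were counted in each isoform they overlapped, so that the second transcript of a gene had a median of 0.889 times the counts of the top transcript. Each gene was therefore represented by the transcript with the highest total over the libraries. The files paired 85864 transcripts with 34980 genes, and 9669 transcripts without a gene, holding 13.96% of the counts, were left out. Gene-level totals ran from 11016841 to 15308781, with 20094 to 20933 genes detected. The most abundant gene, Malat1, took 2.52% to 3.51% of the counts. Without a statement on strand, reads of overlapping genes on opposite strands cannot be told apart. Among named genes at least 10% of the exon bases were shared in Alas2, Bcas1, Bhlhe41, Cryab, Dbp, Grin1, Igf2, Lypd1, Ndufb11, Nefm, Nmbr, Rgs16, Rpl5, Tap2, Tsix, Xist and Zfp296, whose values are uncertain to that extent. Coordinates are those of mm10.

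Groups were taken from the labels. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, with 1 factor of 3 groups over all 6 libraries and 3 residual degrees of freedom. The installed default of the fit (legacy = TRUE) was used. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. All levels are TMM-scaled CPM (counts relative to the scaled library total), with exceptions. The per-library values of Otx2, Xist, Ddx3y, Serpina3n and the choroid plexus markers are scaled by library totals. Where a library had 0 counts, a floor of 3 counts was used, which covers counting error only.

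The lists fixed before the data were examined comprised 31 groups: activity-regulated genes, DNA methylation, parvalbumin and other interneurons, perineuronal nets, critical period brakes, myelinating and precursor oligodendrocytes, astrocytes, microglia, endothelial, meningeal, choroid plexus and blood cells, layers 4, 2/3, 5 and 6, neighbouring brain regions, glutamate and GABA receptors, immature neurons, collagens, heat shock, glucocorticoid response, circadian clock, interferon, Xist and Tsix, Y-linked genes, respiratory chain, ribosomal proteins and mitochondrially encoded genes. The 27 lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. With an estimated correlation, camera takes p from a t distribution with the 3 residual degrees of freedom. A call lost there need not reflect correlation between genes. Counts of members are also given adjusted over the list alone.

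The genes named were set by a rule: Otx2, Gadd45b, Gadd45g and Pvalb; the 8 largest rises and 8 largest falls among genes past the threshold with a mean CPM of 1 or more, groups that did not overlap and a symbol that is not a Gm or Rik name; and up to 4 members of each list with the smallest p among those past the threshold, or the 2 with the smallest p in a called list without such members. The text describes a part of these, and some genes that the rule names are not reported here. Bdnf and genes outside the rule that are named were chosen after their values were seen.

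Both comparisons share the wild-type P30 libraries. Unchanged groups were therefore simulated against shared controls, 100 times for the covariance and 50 times for the overlap of calls. The procedure was tested on simulated data with 200 changed genes among 15608. For age, 50.0%, 75.0% and 95.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 9.9% of calls were unchanged genes. For genotype, the recovered shares were 59.2%, 73.3% and 92.8%, and 8.5% of calls were unchanged genes. Of unchanged lists, 4.5% had a camera p under 0.05. Genes were drawn independently in these simulations, so this share does not cover lists of correlated members. The activity list, for example, had an estimated correlation of 0.316 for age.

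Alternatives were RLE and upper-quartile scaling, no filter, a filter of CPM 1 in 2 libraries, DESeq2 1.42.0, limma-voom, only the 4 libraries compared, a replicate block, and each library left out in turn. Added after seeing the data were the fit with legacy = FALSE, counts summed over transcripts, removal of each library's GC trend, and omission of chromosomes X and Y. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.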

Results

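RNA was sequenced from layer IV of mouse visual cortex, dissected by hand from B6D2 mice that were wild type (Otx2 +/+) or heterozygous for Otx2 (Otx2 +/GFP). Otx2 encodes a homeodomain transcription factor that is made in the choroid plexus and taken up by cortical cells, parvalbumin interneurons among them. Tissue of 4 mice was pooled for each condition, and every condition had 2 libraries. The 6 libraries analysed were 2 from wild-type mice at postnatal day 30 (P30), 2 from wild-type mice at P100 and 2 from heterozygous mice at P30. The 2 heterozygous P100 libraries were not analysed here. Gene-level totals were 11016841 and 14870365 counts at wild-type P30, 13733970 and 11168076 at wild-type P100, and 14842212 and 15308781 at heterozygous P30. After a filter on low counts, 15841 genes were tested. The 2 libraries of a group differed by more than sampling noise, with a chi-square over genes of 4.42 to 5.78 times its degrees of freedom. The labels do not say whether the duplicates came from separate pools of mice, so p-values measure the spread between these libraries, which can be technical.

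The targeted gene could not check the genotype labels. Otx2 (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819, minus strand, mm10) had 0 counts in all 4 wild-type libraries and in heterozygous replicate 1, which allows at most 0.202 to 0.272 CPM at a floor of 3 counts per library. Heterozygous replicate 2 held 73 Otx2 counts, or 4.77 CPM. The same library held 8966 counts (586 CPM) of Ttr, the transthyretin transcript that is abundant in choroid plexus, against 0 or 1 count in each other library. All 17 choroid plexus markers present in the files were highest in that library, each at 2 times the next library or more. Only 3 of them passed the expression filter, and none of these was called over all genes, although all 3 were higher in heterozygotes when adjusted over the list alone (median log2 difference 1.95). Ttr and Otx2 did not pass the filter.

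The genotype groups also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, stood at 789 and 928 CPM in the heterozygous libraries and at 0.269 to 0.635 CPM in the 4 wild-type libraries. Ddx3y, a Y-linked RNA helicase gene, stood at 2.49 and 1.05 CPM in the heterozygous libraries and at 142 to 155 CPM in the wild-type libraries. Every comparison of heterozygous with wild-type P30 tissue was therefore also a comparison of pools with predominantly female and with predominantly male transcripts. The 2 wild-type ages did not differ in this respect: none of the 4 Y-linked genes passed the test between them, with a median log2 difference of 0.01. Neither did Xist or its antisense partner Tsix over all genes, although Tsix was higher at P100 when adjusted over these 2 genes alone.

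**Figure D1:**
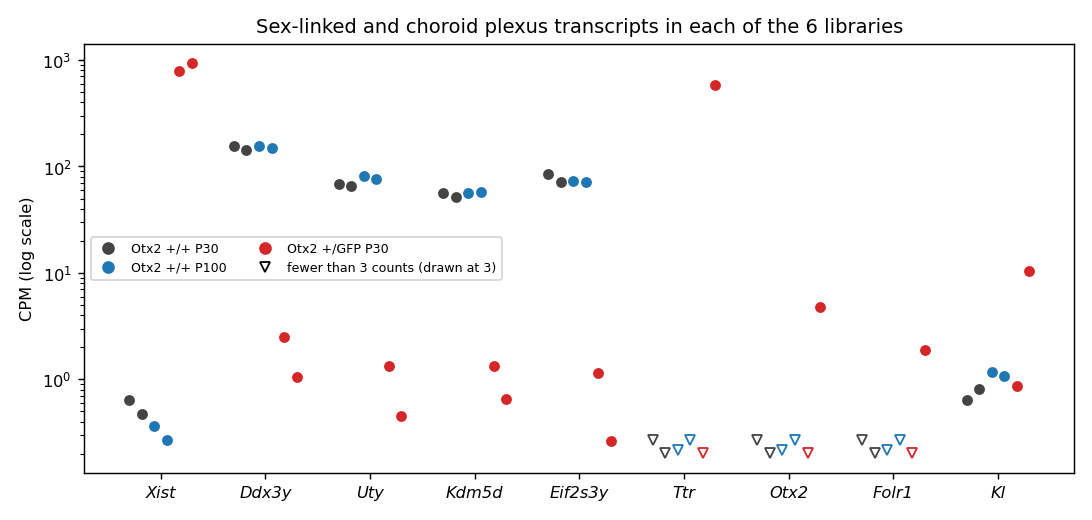
CPM (log axis, scaled by library totals without TMM) of Xist, 4 Y-linked genes and 4 choroid plexus markers in each of the 6 libraries; each point is 1 library, coloured by group, and open triangles stand at the level of 3 counts for libraries with fewer. Xist reaches 789 and 928 CPM in the heterozygous libraries, and Ttr (586 CPM) and Otx2 (4.77 CPM) stand out in heterozygous replicate 2.

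The first comparison set wild-type cortex at P100 against P30, ages after and within the usual span of the critical period for ocular dominance plasticity. Genes induced by neuronal activity were much lower at P100. Of the 30 members of the activity-regulated list, 29 fell and none rose, and all 30 were lower when adjusted over the list alone. The median log2 change was -1.82 (list adjusted p = 0.0976 with an estimated correlation), and Bdnf was the member that did not pass over all genes (log2 difference -0.46, SE 0.16). Egr2, a zinc finger factor of the early response, went from 106.6 ± 16.9 CPM at P30 to 5.46 ± 1.38 CPM at P100 (SD, n = 2 each), 19.3-fold lower. Fos, a subunit of the AP-1 factor, fell 7.80-fold from 200.4 ± 12.9 to 26.0 ± 9.53 CPM. Arc, which encodes a synaptic protein, fell 5.31-fold from 1393 ± 254 to 262 ± 24.1 CPM. The orphan nuclear receptor genes Nr4a1 and Nr4a3 fell 5.33-fold and 5.01-fold. Adjusted p for these 5 genes ran from 1.02e-08 to 5.37e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg).

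**Figure D2:**
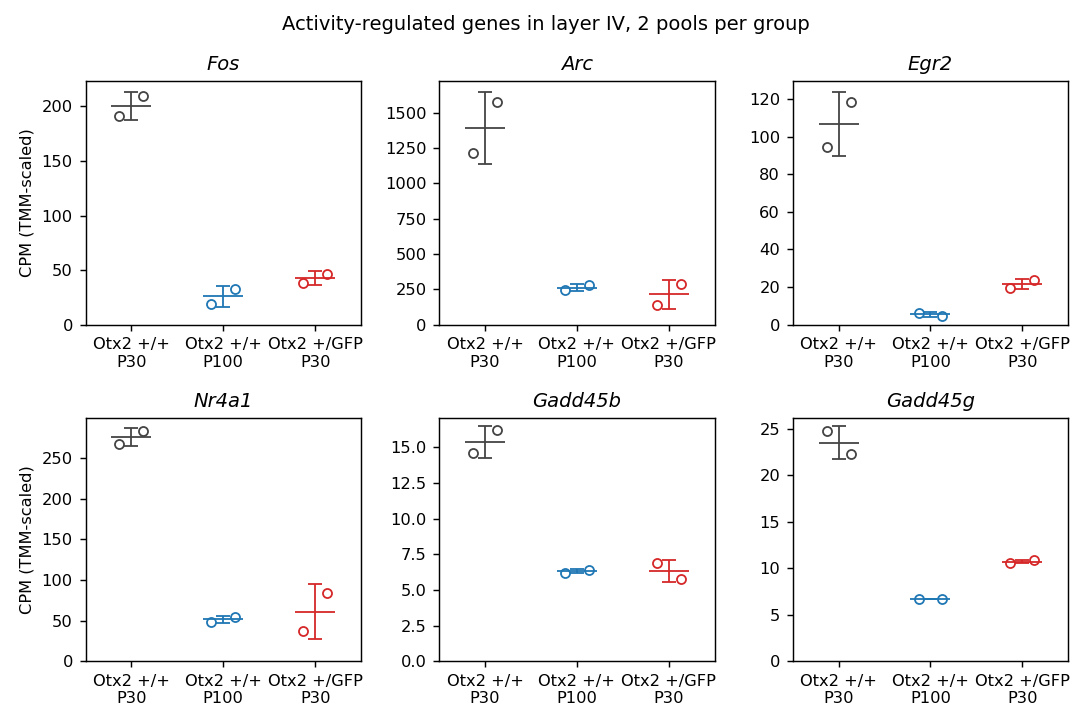
TMM-scaled CPM (linear axes from 0) of 6 activity-regulated genes in wild-type P30, wild-type P100 and heterozygous P30 libraries; circles are the 2 libraries of each group, the horizontal mark is their mean and the bars their SD. Both wild-type P30 libraries lie above every library of the other 2 groups in all 6 panels, for example 200.4 CPM on average for Fos against 26.0 and 42.4.

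Gadd45b and Gadd45g, stress- and activity-induced genes linked to DNA demethylation, both fell with age. Gadd45b (ENSMUSG00000015312, chromosome 10, 80930073 to 80932204, plus strand) went from 15.4 ± 1.12 to 6.32 ± 0.141 CPM (SD, n = 2 each), a log2 change of -1.29 (SE 0.16, edgeR quasi-likelihood adjusted p = 3.44e-04). Gadd45g (ENSMUSG00000021453, chromosome 13, 51846678 to 51848468, plus strand) went from 23.5 ± 1.76 to 6.71 ± 0.0311 CPM, a log2 change of -1.80 (SE 0.14, adjusted p = 6.55e-06 in the same test). Both are on the activity list, so the 2 lists are not separate results for these genes. Both also belong to the DNA methylation and demethylation list, of which 6 of 20 tested members fell and none rose, with 7 lower when adjusted over the list alone. The list median was -0.04 (list adjusted p = 0.238 with an estimated correlation). The de novo methyltransferase gene Dnmt3a fell 1.45-fold and the dioxygenase gene Tet3 fell 2.14-fold. Pvalb (ENSMUSG00000005716, chromosome 15, 78191114 to 78206400, minus strand), the parvalbumin gene itself, stood at 70.0 ± 1.12 CPM at P30 and 74.1 ± 12.9 CPM at P100, with a log2 difference of 0.08 (SE 0.11, adjusted p = 0.708 in edgeR's test).

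Myelin genes were also lower at P100. Of 24 myelinating oligodendrocyte markers, 14 fell and 1 rose, with 18 lower and 1 higher when adjusted over the list alone, and the median log2 change was -0.75 (list adjusted p = 0.107 with an estimated correlation). Cldn11, a tight junction gene of myelin, went from 113.5 ± 11.2 to 36.9 ± 5.58 CPM (SD, n = 2 each). Cnp and Mal fell 2.08-fold and 1.97-fold. Oligodendrocyte precursor and newly formed oligodendrocyte markers fell for 8 of 15 members (10 adjusted over the list alone, median -0.50, list adjusted p = 0.107 with an estimated correlation), among them Gpr17 (2.28-fold) and Enpp6 (4.62-fold). Collagen and basement membrane genes fell for 7 of 24 members (11 adjusted over the list alone, median -0.62, list adjusted p = 0.0976 with an estimated correlation). Sparc, a collagen-binding matrix protein gene, fell 1.74-fold, and Serpinh1, a collagen chaperone gene, fell 2.09-fold.

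Some astrocyte, microglia, endothelial and mural markers fell as well. Of 20 astrocyte markers 5 fell, with 6 lower when adjusted over the list alone (median -0.13, list adjusted p = 0.24 with an estimated correlation). Aqp4, a water channel gene, fell 1.47-fold, and the gap junction gene Gja1 fell 1.38-fold. Microglia markers fell for 4 of 20 members and endothelial and mural markers also for 4 of 20 (6 and 5 adjusted over the list alone, medians -0.32 and -0.29), with a list adjusted p = 0.217 and a list adjusted p = 0.367 with an estimated correlation. Genes of immature neurons and axon growth fell for 5 of 20 members, with 8 lower and 2 higher when adjusted over the list alone (median -0.21, list adjusted p = 0.14 with an estimated correlation). Marcksl1 fell 2.38-fold and Stmn2 1.34-fold. Perineuronal net components and remodelling enzymes fell for 8 of 25 members and rose for 1 (9 and 1 adjusted over the list alone, median -0.16, list adjusted p = 0.172 with an estimated correlation), and the aggrecan-cleaving protease gene Adamts4 fell 2.31-fold. Glucocorticoid-responsive genes fell for 7 of 17 and rose for 1 (9 and 1 adjusted over the list alone, median -0.33, list adjusted p = 0.367 with an estimated correlation): Per1 fell 2.69-fold and Nfkbia 1.73-fold, while the lipid droplet gene Plin4 rose 5.99-fold. Per1 is also on the activity list. Heat shock and protein folding genes fell for 2 of 21 (5 lower and 1 higher adjusted over the list alone, median -0.15, list adjusted p = 0.367 with an estimated correlation).

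In camera tests with the correlation between genes preset at 0.01, these 12 lists were past the threshold among the 27 tested, all downward. Adjusted p was 7.60e-104 for the activity list, 2.08e-37 for myelinating and 1.58e-09 for precursor oligodendrocyte markers and 1.87e-08 for collagens. It was 8.03e-05 for both the DNA methylation and the glucocorticoid lists, 1.27e-04 for microglia, 5.47e-04 for immature neuron genes, 7.70e-04 for endothelial cells, 0.00124 for astrocytes, 0.00170 for perineuronal nets and 0.0419 for heat shock. No list was past it with an estimated correlation, where the activity list had an adjusted p = 0.0976 and the other 11 lists ran from an adjusted p of 0.0976 to 0.367. The heat shock call was lost without wild-type P30 replicate 2 (adjusted p = 0.129), wild-type P100 replicate 2 (0.20), heterozygous replicate 1 (0.0558) or heterozygous replicate 2 (0.0534), and with only the 4 libraries compared (0.0626).

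Neuronal cell type markers did not pass as lists at P100. Parvalbumin interneuron markers rose for 2 and fell for 2 of 22, with 3 and 2 adjusted over the list alone, and the list median of 0.04 lay on the other side of 0 from its mean of -0.05. None of 20 other interneuron markers passed in either count. Among 13 layer 4 markers 1 rose and 1 fell, and among 14 layer 2/3 markers 1 rose and 2 fell. The 2 layer 2/3 falls were Nptx2, which is also on the activity list, and Ptgs2. Their calls were lost under 4 and 3 of 18 alternatives. Layer 5 markers rose for 1 and fell for 2 of 16, and layer 6 markers fell for 1 of 15. Striatal, hippocampal and thalamic markers rose for 2 and fell for 1 of 14. Glutamate and GABA receptor subunits fell for 1 of 24, the NMDA receptor gene Grin1 (1.33-fold). Of 21 critical period brakes and receptors, 2 rose and 1 fell, none of them kept without wild-type P30 replicate 1. Interferon and MHC class I genes rose for 1 and fell for 1 of 18, and meningeal markers fell for 2 of 16. Circadian clock genes went both ways, with 4 of 16 higher and 3 lower: Dbp rose 1.99-fold, whereas Nfil3 fell 2.52-fold. Respiratory chain subunits fell for 4 of 83, ribosomal protein genes rose for 3 of 80, and mitochondrially encoded genes rose for 2 and fell for 2 of 22. Of 4 blood cell markers, too few for a list test, the erythroid gene Alas2 fell, and 3 were lower when adjusted over the list alone (median log2 difference -0.998). The Alas2 call was lost without wild-type P30 replicate 1 (edgeR adjusted p = 0.0962), wild-type P100 replicate 1 (0.123) or wild-type P100 replicate 2 (0.111). None of 3 choroid plexus markers passed in either count. Adjusted over the list alone, 2 layer 4 markers were higher and 2 lower, with 1 and 4 for layer 2/3, 1 and 3 for layer 5, 0 and 2 for layer 6, 2 and 2 for the other brain regions and 5 and 4 for clock genes. In the same count 3 respiratory chain subunits were lower and 1 ribosomal protein gene was higher, and the counts of the other lists here were as over all genes. The median and mean also lay on opposite sides of 0 for the layer 4, clock and interferon lists, and for respiratory chain subunits the median and the camera direction did. Camera adjusted p for these lists ran from 0.0616 to 0.892. Leaving out 1 library gave calls for layer 2/3 markers (adjusted p = 0.00661 without wild-type P30 replicate 1), layer 5 markers (0.00218 without wild-type P100 replicate 1), layer 6 markers (0.00570 without wild-type P100 replicate 1 and 0.00864 without wild-type P30 replicate 2) and mitochondrially encoded genes (0.00219 without wild-type P30 replicate 2 and 0.0223 without wild-type P100 replicate 2). The layer 6 list was also called with a replicate block (adjusted p = 0.0395) and with the GC trend of each library removed (0.0458).

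Across all genes, 475 were higher and 719 lower at P100 (edgeR quasi-likelihood test, adjusted p under 0.05), and 73 and 152 of them differed more than 2-fold. All of the called genes had groups that did not overlap, which held for 51.2% of tested genes and for 33.3% by chance with 2 against 2. Among the 8 largest rises that met the naming rule were low-expressed genes: the flavin monooxygenase gene Fmo2 went from 0.241 ± 0.0462 to 3.21 ± 1.68 CPM (SD, n = 2 each), Plin4 from 1.16 ± 0.614 to 7.28 ± 0.963 CPM, and Bub1b, a mitotic checkpoint gene, from 1.49 ± 0.342 to 5.78 ± 0.215 CPM. The largest falls under the same rule were Tmem252, from 4.54 ± 0.862 to 0.160 ± 0.0221 CPM, Egr2, and the matricellular gene Cyr61, 9.44-fold. In the authors' deposited table, 332 transcripts were higher and 685 lower at an adjusted p under 0.05, and those paired with a gene came from 155 and 308 genes; the log2 change of Gadd45b was -1.28. The counts fell to 227 higher and 375 lower without wild-type P30 replicate 2, to 207 and 385 without wild-type P100 replicate 1, to 118 and 233 without wild-type P100 replicate 2, and the higher count to 257 without wild-type P30 replicate 1. DESeq2 gave 295 higher and counts summed over transcripts 297 higher, while no filter on low counts gave 764 higher and 1096 lower.

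The second comparison set heterozygous against wild-type cortex at P30 and asked which transcripts differ when an Otx2 allele is missing at the critical period age. Activity-regulated genes were lower in heterozygotes: 28 of 30 fell and none rose, all 30 were lower when adjusted over the list alone, and the median log2 change was -1.33 (list adjusted p = 0.115 with an estimated correlation). Arc went from 1393 ± 254 CPM in wild type to 213.9 ± 100.3 CPM in heterozygotes (SD, n = 2 each), 6.51-fold lower. Egr2 fell 4.93-fold, Fos 4.73-fold and Nr4a1 4.53-fold. Gadd45b went from 15.4 ± 1.12 to 6.35 ± 0.785 CPM, a log2 change of -1.28 (SE 0.16, edgeR quasi-likelihood adjusted p = 5.31e-04). Gadd45g went from 23.5 ± 1.76 to 10.7 ± 0.199 CPM, a log2 change of -1.13 (SE 0.13, adjusted p = 3.09e-04 in the same test). Pvalb stood at 70.0 ± 1.12 CPM in wild type and 69.0 ± 2.92 CPM in heterozygotes (log2 difference -0.02, SE 0.11, edgeR adjusted p = 0.946). The same libraries differed in Xist and the Y-linked genes, as given above.

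Among glial groups, myelinating oligodendrocyte markers fell for 15 of 24 members and rose for none, with 23 lower when adjusted over the list alone and a median log2 change of -0.53 (list adjusted p = 0.369 with an estimated correlation). Cldn11 went from 113.5 ± 11.2 to 71.0 ± 0.393 CPM (SD, n = 2 each), Cnp fell 1.48-fold and Gjc3, a connexin gene, 1.76-fold. Astrocyte markers fell for 2 of 20 members (5 adjusted over the list alone, median -0.14, list adjusted p = 0.377 with an estimated correlation). These were Aqp4 and Gfap, whose calls were lost under 4 and 10 of 18 alternatives. Endothelial and mural markers fell for 1 of 20, the tight junction gene Cldn5 (1.77-fold; 1 adjusted over the list alone, median -0.23, list adjusted p = 0.427 with an estimated correlation). Collagen and basement membrane genes fell for 2 of 24 (4 lower and 1 higher adjusted over the list alone, median -0.22, list adjusted p = 0.377 with an estimated correlation). The 2 genes, Serpinh1 and Lamc1, lost their calls under 12 and 2 of 18 alternatives. Oligodendrocyte precursor and microglia markers fell for 2 of 15 and 2 of 20, in both counts, and neither list passed. Choroid plexus markers, by contrast, were high in heterozygous replicate 2.

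Layer markers differed between the genotype groups in both directions. How much of each layer the hand-dissected tissue held was not measured, so layer content cannot be told apart from an effect of genotype. Within groups, the layer 5 members varied together (estimated correlation 0.598). Layer 5 markers rose for 4 of 16 members (8 higher and 1 lower adjusted over the list alone, median 0.37, list adjusted p = 0.437 with an estimated correlation), including Lypd1 (1.67-fold) and Parm1 (1.35-fold). The layer 6 list was called upward with no member past the threshold, in all genes or adjusted over the list alone (median 0.17, list adjusted p = 0.427 with an estimated correlation). That call was lost without wild-type P30 replicate 2 (adjusted p = 0.220) or heterozygous replicate 1 (0.176). Ntsr1 had a log2 difference of 0.94 (SE 0.31, edgeR adjusted p = 0.125) and Rprm of 0.64 (SE 0.22, edgeR adjusted p = 0.139). Layer 4 markers fell for 3 of 13 (4 adjusted over the list alone, median -0.10, list adjusted p = 0.416 with an estimated correlation): Tmem215 fell 1.78-fold, Whrn 1.48-fold and Cux1 1.34-fold. The Cux1 call was lost without wild-type P30 replicate 2 (edgeR adjusted p = 0.163) or heterozygous replicate 2 (0.131), and the Lypd1 call without wild-type P30 replicate 2 (0.156) or heterozygous replicate 1 (0.207) and in DESeq2 (0.122). Parm1 lost its call without any 1 of the 4 libraries compared: adjusted p was 0.0962 and 0.0799 without wild-type P30 replicate 1 and 2, and 0.141 and 0.0554 without heterozygous replicate 1 and 2. It was also lost with counts summed over transcripts (0.0793).

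A few members of stress-related and immune lists fell in heterozygotes. Glucocorticoid-responsive genes fell for 3 of 17 (9 adjusted over the list alone, median -0.31, list adjusted p = 0.377 with an estimated correlation), led by Per1 (2.11-fold). The DNA methylation list fell for 3 of 20 (5 adjusted over the list alone, median -0.11, list adjusted p = 0.377 with an estimated correlation), namely Gadd45b, Gadd45g and Tet3, the last of which was not called without wild-type P30 replicate 2 (edgeR adjusted p = 0.0757) or with counts summed over transcripts (0.0534). Heat shock and protein folding genes fell for 2 of 21 (5 adjusted over the list alone, median -0.21, list adjusted p = 0.377 with an estimated correlation), with the constitutive chaperone gene Hspa8 1.67-fold lower. Interferon and MHC class I genes fell for 2 of 18 (6 adjusted over the list alone, median -0.72, list adjusted p = 0.369 with an estimated correlation): the peptide transporter gene Tap2 and the class I gene H2-D1, with log2 changes of -0.94 (SE 0.23) and -0.84 (SE 0.21). Both calls were lost without any 1 of the 4 libraries compared: edgeR adjusted p for Tap2 and H2-D1 was 0.118 and 0.175 without wild-type P30 replicate 1, 0.113 and 0.0892 without wild-type P30 replicate 2, 0.282 and 0.187 without heterozygous replicate 1, and 0.0726 and 0.131 without heterozygous replicate 2. Tap2 was also not called without wild-type P100 replicate 1 or 2 (adjusted p = 0.0606 and 0.0559) or with only the 4 libraries compared (0.0602). The H2-D1 call was lost under 11 of 18 alternatives: beside these 4, with upper-quartile scaling (adjusted p = 0.0536), the stricter filter on low counts (0.0506), the fit with legacy = FALSE (0.0517), DESeq2 (0.0550), limma-voom (0.0598), summed transcripts (0.0863) and the GC trend removed (0.0579). Tap2 and H2-D1 lie on chromosome 17, as do the list members H2-K1 and H2-T23, which were not called. Scaled by library totals, each of these genes was lower in both heterozygous libraries than in both wild-type P30 libraries. Across the list, 15 members lay below 0 and 3 above.

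These 12 lists were past the threshold among 27 in camera with the preset correlation. Adjusted p was 5.95e-90 for the activity list, 1.64e-23 for myelin, 3.32e-06 for glucocorticoid response, 2.61e-04 for both layer 5 and interferon genes, 5.93e-04 for heat shock, 0.00199 for DNA methylation, 0.00452 for astrocytes, 0.00673 for endothelial cells, 0.0294 for layer 4, 0.0408 for layer 6 and 0.0416 for collagens. With an estimated correlation none was past it; the activity list had an adjusted p = 0.115, and the other 11 lists ran from an adjusted p of 0.369 to 0.437. Leaving out 1 library ended the collagen call (adjusted p = 0.210 without wild-type P30 replicate 1, 0.0730 without heterozygous replicate 1 and 0.0938 without heterozygous replicate 2) and the layer 4 call (0.162 without wild-type P30 replicate 2 and 0.173 without heterozygous replicate 2). It also ended the layer 6 call (0.220 without wild-type P30 replicate 2 and 0.176 without heterozygous replicate 1), the endothelial call (0.0917 without wild-type P30 replicate 1 and 0.0730 without heterozygous replicate 1) and the astrocyte call (0.0730 without heterozygous replicate 1). The collagen call was also lost with a replicate block (adjusted p = 0.0681) and with only the 4 libraries compared (0.0519), and the layer 4 call with the GC trend of each library removed (0.109).

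The remaining lists did not pass, with camera adjusted p from 0.0612 to 0.926. Parvalbumin interneuron markers fell for 2 of 22, Nefm and Kcna1, and rose for none; the Kcna1 call was lost without wild-type P30 replicate 2 (edgeR adjusted p = 0.128), heterozygous replicate 1 (0.290) or heterozygous replicate 2 (0.114), and with counts summed over transcripts (0.0735). None of 20 other interneuron markers passed over all genes, but 4 were higher and 2 lower when adjusted over the list alone. Perineuronal net genes fell for 2 of 25, critical period brakes and receptors for 1 of 21, layer 2/3 markers for 2 of 14, meningeal markers for 1 of 16, and glutamate and GABA receptor subunits for 2 of 24. The layer 2/3 falls were Ptgs2 and Nptx2, the latter also on the activity list and lost under 3 of 18 alternatives. The perineuronal net calls, Adamts4 and Tnr, were lost under 4 and 9 of 18 alternatives. Those of the receptor subunits, Grin1 and Grin2b, were lost under 10 and 5 of 18. None of the 14 striatal, hippocampal and thalamic markers, 20 immature neuron genes, 83 respiratory chain subunits or 80 ribosomal protein genes passed over all genes, and 1 of 22 mitochondrially encoded genes rose. The call of that gene, mt-Tl1, was lost under 6 of 18 alternatives. Circadian clock genes rose for 4 and fell for 4 of 16, with Dbp 2.65-fold higher and Nfil3 3.60-fold lower. None of 4 blood cell markers passed over all genes, and 2 were lower when adjusted over the list alone (median -0.52). In that count 3 immature neuron genes were higher and 1 lower, 5 clock genes were higher and 6 lower, and 3 layer 2/3 markers and 2 critical period brakes and receptors were lower. The list-alone counts of the other lists here were as over all genes. Without wild-type P30 replicate 1 the test called the clock (adjusted p = 0.0271), layer 2/3 (0.00115), immature neuron (0.0387), respiratory chain (0.0337) and mitochondrially encoded (0.0346) lists. Without wild-type P30 replicate 2 it called microglia (adjusted p = 0.0383), and without heterozygous replicate 2 microglia (0.0165), other interneurons (0.0359) and mitochondrially encoded genes (0.0244). Immature neuron genes were also called upward with the stricter filter on low counts (adjusted p = 0.0419) and with the GC trend removed (0.0405).

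Across all genes, 143 were higher and 368 lower in heterozygotes (edgeR quasi-likelihood test, adjusted p under 0.05), of which 30 and 94 differed more than 2-fold. All called genes had groups that did not overlap, against 48.9% of tested genes and 33.3% by chance. The largest falls were the 4 Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d (55.1-fold to 113.8-fold), followed by Tmem252, Cyr61 (6.97-fold), Serpina3n (6.80-fold) and Arc. Among genes that met the naming rule, whose mean CPM of 1 or more leaves out Tsix, the largest rises were Xist, the scavenger receptor gene Stab2 (0.333 ± 0.175 to 5.35 ± 3.43 CPM; SD, n = 2 each), Fmo2 (0.241 ± 0.0462 to 3.64 ± 0.542 CPM) and Nmbr, which encodes the neuromedin B receptor (0.311 ± 0.0521 to 2.44 ± 0.323 CPM). Serpina3n was not past the threshold without wild-type P30 replicate 2 (adjusted p = 0.0756 in edgeR's test), with summed transcripts (0.0721) or in DESeq2 (0.115). Scaled by library totals, Serpina3n stood at 17.6 and 18.6 CPM at wild-type P30 and at 3.44 and 2.025 CPM in heterozygotes. The wild-type P100 libraries held 20.8 and 3.13 CPM, so 1 wild-type library lay within the heterozygous range. Without chromosomes X and Y the counts were 136 higher and 358 lower. In the authors' deposited table, 170 transcripts were higher and 610 lower at an adjusted p under 0.05, and those paired with a gene came from 77 and 259 genes; the log2 change of Gadd45b was -1.27. The counts fell to 52 higher and 147 lower without wild-type P30 replicate 2 and to 55 and 129 without heterozygous replicate 1, and the higher count to 78 without heterozygous replicate 2, the library with choroid plexus transcripts. DESeq2 gave 94 higher, counts summed over transcripts 71 higher and 192 lower, and no filter on low counts 392 higher and 728 lower.

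Both comparisons used the same 2 wild-type P30 libraries. There were 208 genes lower in both, 46 higher in both and 5 that went opposite ways. Independent lists of these sizes would share 16.7 lower and 4.29 higher genes, and unchanged groups simulated against shared controls gave at most 1 of either in 50 simulations. Those simulations held no changed gene, so a nearly empty overlap was given in advance. They cannot show how many of the shared calls come from the shared controls. Of the 30 activity-regulated genes, 28 were lower in both. Myelinating oligodendrocyte markers lay below 0 for 22 of 24 members with age and for all 24 in heterozygotes. For these markers too, a trait of the shared wild-type P30 libraries cannot be told apart from effects of age and genotype. Across 15841 genes the log2 changes had a covariance of 0.0680, against a mean of 0.0273 in 100 simulations of unchanged groups, a difference of 0.0407, and the highest simulated covariance was 0.0293. Their correlation across genes was 0.50, against 0.52 in the simulations, and 67.3% of genes had the same sign, against 67.1%. The controls could not be split into parts of 2 libraries, so part of the shared calls may come from the shared controls. When heterozygous P30 was set directly against wild-type P100, 6 of 30 activity-regulated genes were higher in heterozygotes and none lower, with a median log2 difference of 0.17.

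**Figure D3:**
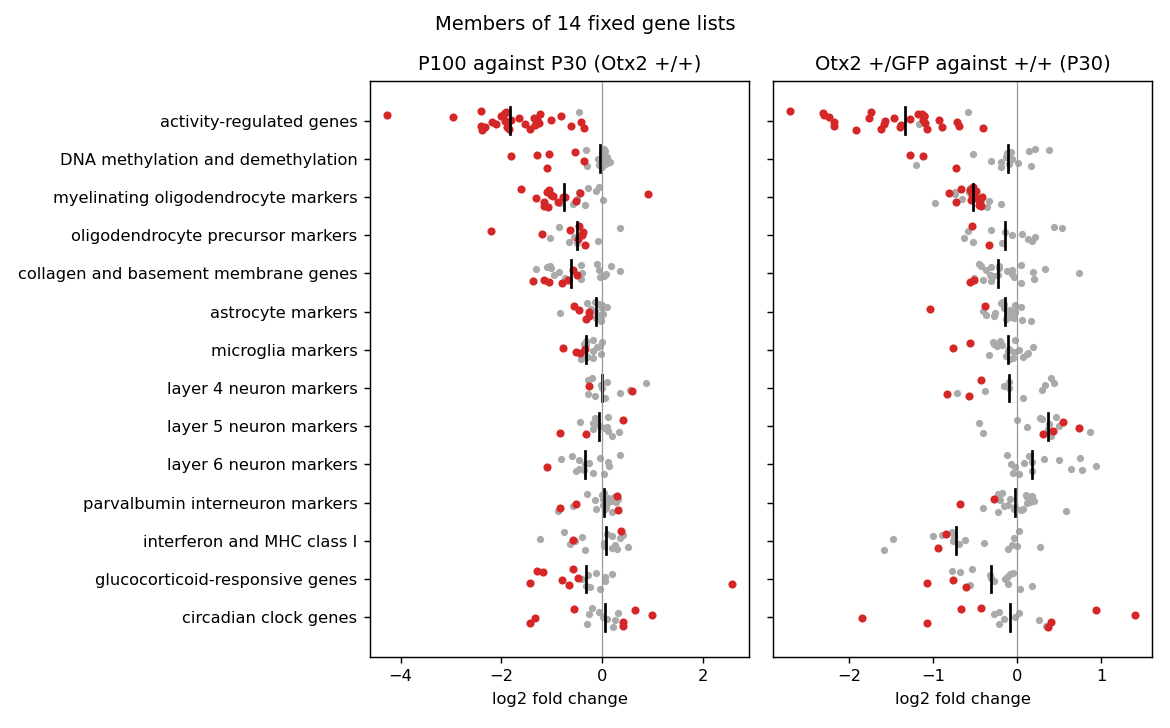
Log2 fold changes (horizontal axes) of the tested members of 14 gene lists fixed in advance, for P100 against P30 in wild type (left) and heterozygous against wild type at P30 (right); each point is a gene, red where its edgeR adjusted p is under 0.05 and grey otherwise, and black bars mark list medians. The activity-regulated list has medians of -1.82 and -1.33, and the layer 5 list a median of 0.37 on the right.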

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

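The tests of choroid plexus tissue and of a swapped library were chosen after the result was seen. Heterozygous P30 replicate 2 stood apart from the other 5 libraries in choroid plexus transcripts, and 3 of the 17 markers entered the tests. Ttr reached 585.7 CPM and Otx2 4.769 CPM in that library, above the limit that a count of 0 allows in the wild-type libraries. All 17 choroid plexus markers in the files were highest there, at 2 times the next library or more, and Kl, Clic6 and Kcne2 stood at 10.5, 6.01 and 5.94 CPM. A wild-type library in its place is argued against by the Y-linked genes, whose highest ratio to the lowest wild-type library was 0.01271. Choroid plexus tissue in that pool is a candidate source of these transcripts; the list was fixed before the data were examined, and no biological explanation was tested.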

How the results depend on the processing

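The fit with legacy = FALSE, summed transcripts, removal of the GC trend, the omission of chromosomes X and Y and the covariance without the activity list and those chromosomes were chosen after the result was seen. No named gene that was called reversed its direction under any alternative. Of the named genes called, 38 of 95 for age and 31 of 62 for genotype kept their call under every alternative that gave an adjusted p; DESeq2 gave none for 4 and 11 named genes. With no filter on low counts, which tested 24034 genes, 764 genes were higher and 1096 lower at P100, and 392 were higher and 728 lower in heterozygotes. DESeq2 called 295 higher at P100 and 94 higher in heterozygotes. Counts summed over transcripts gave 297 higher at P100, and 71 higher and 192 lower in heterozygotes. With an estimated correlation 0 lists were past the threshold for age and 0 for genotype. For age, the estimated correlation was 6.07e-04 for the collagen list and 0.00567 for perineuronal nets, below the preset 0.01. Their camera p before adjustment still rose from 2.76e-09 to 0.00723 and from 6.93e-04 to 0.0382. A higher correlation therefore does not explain the loss of these calls. With an estimated correlation, camera used a t distribution with the 3 residual degrees of freedom, which by itself raises p at a given statistic. The causes of the other shifts were not tested further, except that no filter adds genes. Leaving out 1 library gave 118 to 417 higher and 233 to 661 lower at P100, and 52 to 116 higher and 129 to 376 lower in heterozygotes; a group left with 1 library was assumed to vary like the others. It gave 11 to 14 lists for age, 9 to 16 for genotype and covariances of 0.0712 to 0.116, against 0.0303 to 0.0663 simulated for unchanged groups (differences of 0.0385 to 0.0495). The other settings stayed within 1.5 times the reported counts. The covariance was 0.0638 without the activity list and chromosomes X and Y, against 0.0272 simulated, a difference of 0.0366.

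The replicate numbers shared by the labels mark no stated litter or day, and the correlations of same-numbered deviations were -0.0041, 0.10 and -3.15e-04. With a replicate block, 526 genes were higher and 794 lower at P100, 192 were higher and 450 lower in heterozygotes, and 13 and 11 lists were past the threshold.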

Other observations

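The tests of gene families, and all tests weighed here except that of segregating alleles, were chosen after the result was seen, as were the genes named in this paragraph. Among 248 families of shared symbol, zinc finger genes with the prefix Zfp, mostly DNA-binding proteins, rose with age for 38 of 332 members and fell for 3 (median log2 change 0.14, camera adjusted p = 8.79e-05, but adjusted p = 0.997 with an estimated correlation). Zfp101 went from 24.8 ± 3.25 to 47.9 ± 2.49 CPM (SD, n = 2 each; edgeR adjusted p = 2.21e-04). Tetraspanin genes fell for 6 of 16 members (median -0.33, camera adjusted p = 6.87e-05, but adjusted p = 0.997 with an estimated correlation), among them Tspan2, a myelin gene on the oligodendrocyte list, with a log2 change of -1.15 (SE 0.098). With the GC trend removed, adjusted p was 0.00276 for Zfp and 0.00369 for tetraspanins. Of the 5 families past the threshold for age, the other 3 (Hist, Dusp and Adamts) lost their call with the GC trend removed, as did all 3 for genotype (Irf, Dusp and Kdm), while Haus gained a call for age. In heterozygotes, the neighbouring chromosome 4 genes Alad, of heme synthesis, and Hdhd3 were higher, with log2 changes of 1.20 (SE 0.18, edgeR adjusted p = 0.00265) and 1.53 (SE 0.27, edgeR adjusted p = 0.00739).

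Activity-regulated genes were lower both at P100 and in heterozygotes than at wild-type P30. The smaller of the 2 median falls was 4.632 times the largest median difference between 2 libraries of a group, which argues against noise of the size seen between duplicates. If duplicates share a pool of mice, their difference does not measure the spread between pools, and the ratio cannot weigh that spread. The list differed between heterozygous P30 and wild-type P100 by 0.126 of the smaller median fall. An acute state of the wild-type P30 mice at collection (light, handling, arousal) could therefore give the same values. Such a state cannot be told apart from effects of age and genotype. Another clock phase at collection stays open too. Evening genes (Dbp, Tef, Hlf, Per2, Per3, Nr1d1, Nr1d2 and Bhlhe41) were set against morning genes (Arntl, Clock, Npas2 and Cry1). The evening mean exceeded the morning mean by 0.296 for age (exact permutation p = 0.2, two-sided) and by 0.634 for genotype (exact permutation p = 0.0404, two-sided). Per1 and Nfil3, which fell in both comparisons, were in neither group. The permutation was over genes, so its p-values do not measure the spread between mice.

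Of the genes that differed between the genotypes, 2.544% were on the X chromosome. X-linked genes were called for 13 of 631 and autosomal genes for 484 of 14929 (Fisher's exact p = 0.105, two-sided), which argues against X dosage as the source of most calls. Neighbours were counted among called genes with coordinates on the autosomes or the X chromosome, outside the activity list and without Xist and Tsix. Of these, 137 of 467 had a called neighbour of the same direction within 1 Mb. The mean was 145.6 in 10000 shuffles (permutation p = 0.7634, one-sided), so such neighbours were not in excess. Alleles that act on scattered genes or in both directions would give no such excess. The count therefore cannot decide whether alleles that segregate in the mixed B6D2 strain were a source of calls. For the neighbours Alad and Hdhd3 a local block of alleles stays open, as it does for the chromosome 17 genes Tap2, H2-D1, H2-K1 and H2-T23. Sex differences other than X and Y dosage may contribute and cannot be told apart from genotype, since 0 libraries of either genotype shared the sex of the other.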
